A study of Mus musculus with 5 samples.

How the data were processed

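RNA pulled down with tagged ribosomes was measured in dissected cerebral cortex (2 libraries) and dentate gyrus (3 libraries) of adult mice. The mice carry the KL100 Rbp4-Cre driver and a Cre-dependent EGFP-tagged ribosomal protein. The method, translating ribosome affinity purification (TRAP), uses an antibody against EGFP to pull down tagged polysomes from a tissue homogenate, so that the RNA of the cells expressing Cre is enriched over that of their neighbours. Per the labels' protocols, the tissues were homogenized separately and all 5 libraries are immunopurified fractions. No unpurified input or untagged control was analysed here, so enrichment over whole tissue and background binding to the beads were not measured.

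The deposited values are raw read counts per gene symbol, 1 table per library. Per the submitters' processing notes, reads were handled with STAR 2.0.0e and HTSeq on the mm10 build. The HTSeq version, the gene annotation, the strand setting and the treatment of overlapping genes are not given in the sources used here. Reads of a gene and of an overlapping antisense gene may therefore share a count. Reads that matched several places were set aside in the deposited counts in a separate class, which can lower genes with near-identical copies such as ribosomal protein genes. The summary classes that name no gene were left out of library sizes and tests. Reads without a feature were 10.59% and 11.0% of all counted reads in cortex replicates 1 and 2, and 13.26%, 13.52% and 14.83% in dentate gyrus replicates 1, 2 and 3. Reads that were not unique were 29.95% and 31.76% in the cortex libraries and 25.13%, 25.44% and 25.03% in the dentate gyrus libraries. Ambiguous reads were 1.81% to 1.87% in each library.

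The files listed 32531 genes, of which 18950 had at least 1 count in a library. Total gene counts ran from 22600963 to 36837908 per library. A floor of 3 counts corresponded to 0.0814 to 0.133 counts scaled to library size (counts per 1e6, CPM) in single libraries, to 0.0505 CPM over the cortex libraries together and to 0.0356 CPM over the dentate gyrus libraries together. Folds against a tissue with 0 counts were computed against the floor over that tissue and are given as lower bounds. Floors and counting intervals cover counting error only, because the reads carried no molecular identifiers that were used here.

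The comparison was made with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by trimmed mean of M values (TMM), low genes were removed with filterByExpr, and a quasi-likelihood F test was run on tissue alone for 14136 genes, dentate gyrus minus cortex. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values for genes in the text come from this test unless another is named. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Fold changes are given on the log2 scale with a standard error (SE). Libraries were compared by Spearman correlation of log2 CPM with a prior count of 2 and by principal components.

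Gene lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera asks whether the members of a list shift toward one tissue relative to other genes. A list whose members change in both directions can therefore fail to pass. Lists with at least 3 tested members entered, 34 of 35, and p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists held markers of regional neuron types, markers of other cells that the dissection could hold, and functional gene families. These lists, the groups, the edgeR and camera tests and the alternatives were fixed before the data were examined, apart from the additions named below. The short lists of cerebellar and subiculum markers were drawn up later, in part after values were seen.

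Named genes followed a rule fixed at the same time. It took the 12 largest changes in each direction among called genes with a mean count of at least 100 in the higher tissue and no overlap between tissues, leaving out predicted loci, microRNA, snoRNA and pseudogene symbols, of which 103 met the criteria. It also took up to 4 members of each list with the smallest adjusted p, and 8 genes chosen in advance. Genes named outside this rule are identified as chosen after their values were seen. Gene positions are from GENCODE M21 on GRCm38, the same build as mm10.

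The procedure was tested on simulated counts for the dentate gyrus against cortex comparison, drawn from the means and library sizes of the real libraries over 14136 genes, of which 13690 passed the filter. It recovered 24 of 99 genes changed 2-fold (24.2%) and 54 of 98 genes changed 4-fold (55.1%), with 9 false calls among 87 calls, and called 0 of 50 lists without a change. Small changes were therefore under-counted in the simulation and may be so here, and false calls took a larger share there than the threshold of 0.05. Far fewer genes changed in the simulation than the 3009 called in the data, so these shares may not carry over.

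The alternatives were 2 other scalings, no filter and a stricter filter, a replicate block, robust dispersion, leaving out each library, DESeq2 1.42.0, limma voom, a test for changes above 2-fold, an estimated inter-gene correlation, and other settings of the similarity. Removal of the ribosomal RNA precursor Rn45s, and removal of cortex replicate 1 together with dentate gyrus replicate 2, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.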

Results

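The data describe RNA pulled down with tagged ribosomes from 2 brain regions of adult mice. Without an input or untagged control, how much of it came from tagged neurons and how much was background was not measured. The Rbp4-Cre KL100 line is widely used to express Cre recombinase in pyramidal neurons of cortical layer 5, which the labels do not state, and the series names neurons of cerebral cortex and dentate gyrus as its subject. There were 2 libraries from cerebral cortex and 3 from dentate gyrus, the granule cell layer region of the hippocampal formation. Gene counts summed to 34887421 and 23967356 in cortex replicates 1 and 2, and to 36837908, 22600963 and 25670171 in dentate gyrus replicates 1, 2 and 3. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

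Genes needed as background were read first. Rbp4, whose regulatory sequence drives Cre (chromosome 19, 38116629 to 38125281 on the minus strand), was at 12.5 ± 3.53 CPM in cortex (SD, n = 2) and 7.6 ± 3.64 CPM in dentate gyrus (SD, n = 3), with an adjusted p of 0.407 by edgeR. Counts per gene symbol do not separate endogenous Rpl10a from the tagged copy of this ribosomal protein gene. Rpl10a was at 0.726 ± 0.505 and 0.856 ± 0.363 CPM. This low value is uncertain because reads shared with near-identical copies were not counted. General neuronal genes were abundant in all libraries. Snap25, a synaptic vesicle fusion protein, was at 32633 ± 3660 CPM in cortex and 19315 ± 1363 CPM in dentate gyrus, a log2 fold change of -0.76 (SE 0.08). The vesicular glutamate transporter gene Slc17a7 was also lower in dentate gyrus (log2 -0.87, SE 0.13), whereas the kinase gene Camk2a (0.77, SE 0.09) and the neuronal splicing factor gene Rbfox3 (0.83, SE 0.14) were higher there. The Rbfox3 adjusted p was 0.0505 without cortex replicate 1 and dentate gyrus replicate 2 together. The ribosomal RNA precursor Rn45s took 1.78% and 2.37% of gene counts in the cortex libraries and 0.891% to 1.01% in the dentate gyrus libraries.

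Libraries of the same tissue resembled each other more than libraries of different tissues. Spearman correlations across genes of log2 CPM were 0.9534 to 0.9569 within a tissue and 0.8747 to 0.8967 between tissues, and genes are not independent replicates. The leading principal component held 55.3% of the variance and separated the tissues. Counts of libraries from the same tissue differed by more than counting noise, with a chi-square per degree of freedom of 41.3 to 57.9, so none was a repeat read of another library. This does not show that they came from separate animals.

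The main question was which transcripts in the pulled-down RNA differ between dentate gyrus and cortex. Transcripts of dentate granule cells were far more abundant in dentate gyrus, while most activity-regulated genes and some genes of cortical layers and of interneurons were more abundant in cortex. Prox1, the homeobox gene of granule cell identity (chromosome 1, 190118035 to 190170714, minus strand), was at 1057 ± 104 CPM in dentate gyrus and 8.53 ± 8.71 CPM in cortex. Deptor, an inhibitor of the mTOR kinase (chromosome 15, 55112317 to 55259271, plus strand), was at 190 ± 12.1 CPM in cortex and 6.46 ± 6.61 CPM in dentate gyrus. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3009 of 14136 genes differed (21.3%), of which 1481 were higher in dentate gyrus and 1528 higher in cortex. A fitted change of at least 4-fold was found for 368 genes toward dentate gyrus and 645 toward cortex. All but 1 of the called genes had no overlap between tissues, as had 50.1% of all tested genes, where 20% is given by chance. The count was 1906 without cortex replicate 1, 1886 without cortex replicate 2, 1578 without cortex replicate 1 and dentate gyrus replicate 2 together, and 842 when the change had to exceed 2-fold.

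**Figure D1:**
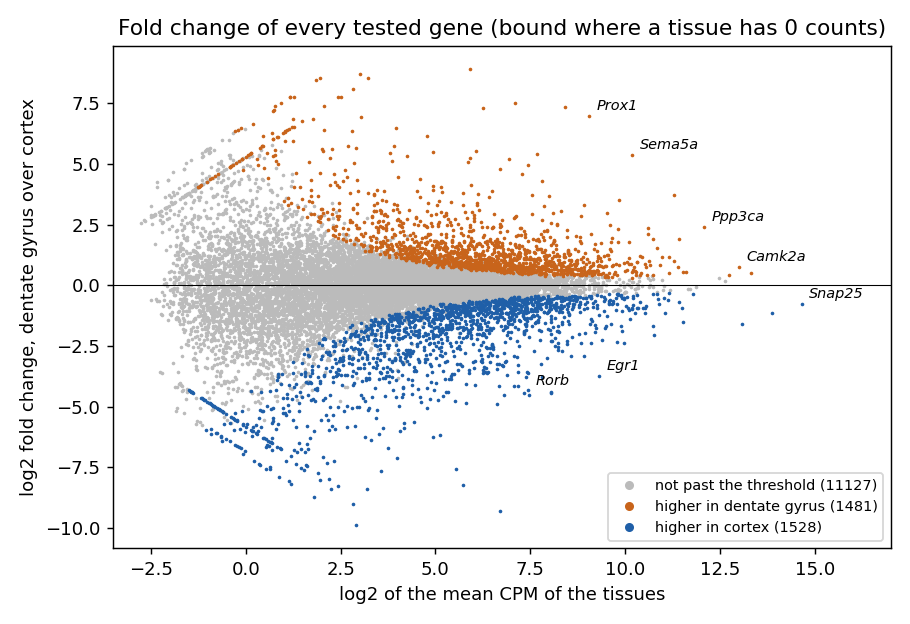
The log2 fold change of dentate gyrus over cortex (vertical axis) is plotted against the log2 of the mean CPM of the tissues (horizontal axis) for 14136 tested genes, with genes at 0 counts in a tissue drawn at their bound and genes past an adjusted p of 0.05 coloured. The 1481 genes higher in dentate gyrus and the 1528 higher in cortex are drawn in separate colours, and the smallest called changes are at high abundance.

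The largest changes were in genes of low abundance that were nearly silent in the other tissue. Toward dentate gyrus, Zcchc5 was at 18.8 ± 8.04 CPM and Usp50, a member of the ubiquitin-specific protease family, at 10.9 ± 4.73 CPM, each with 0 counts in cortex, which makes them at least 372-fold and at least 216-fold higher. Clec1a, Best3, Cyth4, Il20rb, Islr and Pla2g2f, also at 0 counts in cortex, were at least 166-fold, 111-fold, 92.8-fold, 81.5-fold, 80.7-fold and 78.1-fold higher. The Pla2g2f adjusted p was 0.0850 without cortex replicate 1 and dentate gyrus replicate 2 together. Lct, the lactase gene, was the most abundant of this set at 121 ± 27.5 CPM against 0.275 ± 0.308 CPM. The transcription factor gene Cebpd and the phospholipase gene Pla2g2d were at 16.1 ± 4.25 and 7.69 ± 6.0 CPM in dentate gyrus and under 0.05 CPM in each cortex library, and the Pla2g2d adjusted p was 0.0575 by limma voom. Il13ra1 rested on dentate gyrus replicate 1, with 12 CPM against 0.755 and 0.431 CPM in replicates 2 and 3, and its adjusted p was 0.0709 without that library, and 0.101 and 0.0918 without cortex replicates 1 and 2. Toward cortex, the integrin gene Itgb3 was at 10.9 ± 6.87 CPM (chromosome 11, 104608000 to 104670476, plus strand) and at least 306-fold higher. Fbln7, Dkkl1, Xirp2 and the transcription factor gene Sim1, also at 0 counts in dentate gyrus, were at least 256-fold, 212-fold, 172-fold and 169-fold higher. Cortex replicate 2 gave most of the Itgb3 and Xirp2 values, with 15.8 and 8.94 CPM against 6.05 and 3.34 CPM in replicate 1. Tmem232 was at least 129-fold higher, but it was at 2.31 and 6.89 CPM in cortex replicates 1 and 2, and its adjusted p was 0.0684 without replicate 2. Igfn1, Col8a1, Tgm3 and Susd5 were at 15.1 ± 3.13, 14.1 ± 1.56, 18.2 ± 5.95 and 9.44 ± 0.117 CPM in cortex and had 1, 2, 4 and 2 counts over the dentate gyrus libraries. Bmper and Car8 differed between the cortex libraries. Bmper was at 5.67 and 0.574 CPM in cortex replicates 1 and 2. Car8 was at 411 CPM in cortex replicate 1 and 1.44 CPM in replicate 2, and its adjusted p was 0.545 without cortex replicate 1.

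All 19 dentate granule cell markers were higher in dentate gyrus, also when adjusted over the list alone, with a median log2 fold change of 4.32. Stxbp6, a syntaxin-binding protein gene, was at 1676 ± 120 CPM in dentate gyrus and 148 ± 21.6 CPM in cortex. Dock10, a guanine nucleotide exchange factor gene, was at 428 ± 13.7 and 21.5 ± 4.35 CPM. The Notch coactivator gene Maml2 was at 339 ± 35.4 and 10.8 ± 2.97 CPM, and the transcription factor gene Rfx3 had a log2 change of 3.0 (SE 0.16). Camera gave an adjusted p of 2.53e-48 for the list, and the adjusted p was 0.116 with an estimated correlation. Of 5 tested immature granule neuron markers, 2 were higher in dentate gyrus, the transcription factor genes Neurod1 (log2 2.80, SE 0.22) and Sox11 (1.72, SE 0.32). Dcx was at 16.0 ± 5.54 CPM in dentate gyrus and 24.1 ± 3.41 CPM in cortex and did not pass. Sox4 had a log2 change of -1.72 and did not pass, but without dentate gyrus replicate 1 it was higher in cortex (log2 -3.85, adjusted p 0.0160). The list had a median of -0.10, a mean of 0.42 and a camera direction toward dentate gyrus with an adjusted p of 0.139. That p was 0.0108 without cortex replicate 1 and dentate gyrus replicate 2 together.

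Markers of neighbouring hippocampal cells did not move as groups. Of 3 tested mossy cell markers, the dopamine receptor gene Drd2 was higher in cortex (10.5 ± 8.93 against 1.21 ± 0.641 CPM), with an adjusted p of 0.0210 that became 0.404 without cortex replicate 2. Of 11 hippocampal CA pyramidal markers, 2 were higher in dentate gyrus and 3 in cortex, or 3 and 3 when adjusted over the list alone, and 0 and 1 without cortex replicate 1. By DESeq2 the counts were 4 and 3. Coch, an extracellular matrix gene, was at 52.0 ± 18.2 CPM in cortex and 2.74 ± 2.03 CPM in dentate gyrus. The camera adjusted p was 0.6 for mossy cell markers and 0.928 for CA pyramidal markers.

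**Figure D2:**
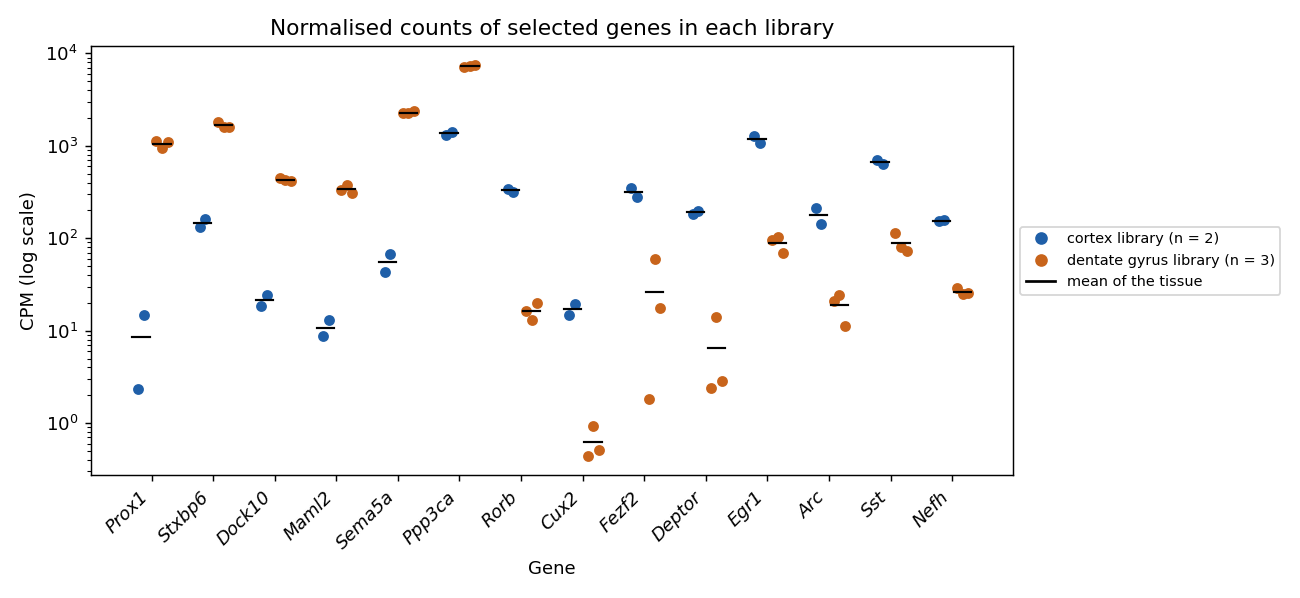
CPM on a log scale (vertical axis) is shown for 14 genes (horizontal axis), with a point for each of 2 cortex and 3 dentate gyrus libraries and a line at the mean of each tissue. Prox1 was near 1057 CPM in dentate gyrus and 8.53 CPM in cortex, and the Fezf2 values of the 3 dentate gyrus libraries spread from 1.82 to 60.2 CPM.

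Among 7 transcription factor genes of cortical projection neurons, 4 were higher in cortex and 2 in dentate gyrus, the same counts as when adjusted over the list alone. The myocyte enhancer factor gene Mef2c had a log2 change of -1.39 (SE 0.09). Neurod2 (2.01, SE 0.15) and Lmo3 (1.33, SE 0.12) were higher in dentate gyrus. Camera gave an adjusted p of 0.149, which became 0.0399 without dentate gyrus replicate 2, and 0.0444 with a replicate block.

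Layer 5 genes did not move as a single set. Of 13 pyramidal tract markers, 4 were higher in cortex and 3 in dentate gyrus, also when adjusted over the list alone, and 2 and 3 with robust dispersion. Fezf2, the selector gene of subcerebral projection neurons (chromosome 14, 12342094 to 12348189, minus strand), was at 353 and 283 CPM in the cortex libraries. In dentate gyrus replicates 1, 2 and 3 it was at 1.82, 60.2 and 17.5 CPM. Its log2 change was -3.60 (SE 0.91, adjusted p 0.0190), and the adjusted p was 0.0652 without cortex replicate 1, 0.0586 without dentate gyrus replicate 3 and 0.217 with robust dispersion. Bcl11b, which acts with Fezf2 in corticospinal neurons, was higher in dentate gyrus (332 ± 33.5 against 93.8 ± 8.97 CPM). Thsd7a (1.34, SE 0.16) and Fam84b (1.62, SE 0.28) were also higher in dentate gyrus, and Parm1 was higher in cortex (-1.83, SE 0.30). The list median was -0.25 and its mean -0.63, whereas the camera direction was toward dentate gyrus, with an adjusted p of 0.876. Of 8 layer 5 intratelencephalic markers, 3 were higher in cortex and 0 in dentate gyrus, or 6 and 1 when adjusted over the list alone, and 5 were higher in cortex without dentate gyrus replicate 2. Deptor had a log2 change of -4.90, and the transcription factor gene Etv1 was at 256 ± 40.0 and 66.2 ± 27.2 CPM. The median log2 change was -3.65 and the camera adjusted p was 0.0121, or an adjusted p of 0.522 with an estimated correlation. Of 4 near-projecting markers, Tshz2 was higher in cortex and the thyrotropin-releasing hormone receptor gene Trhr in dentate gyrus. Tshz2 was at 118 ± 9.27 and 13.5 ± 15.7 CPM, and its adjusted p was 0.107 with robust dispersion. Trhr had an adjusted p of 0.0210, which became 0.124 without cortex replicate 1. The near-projecting list had a median of 0.30, a mean of -0.25 and a camera adjusted p of 0.928.

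Some markers of other cortical layers were higher in cortex, a few were higher in dentate gyrus, and others were not called. Of 11 layer 2 to 4 markers, 4 were higher in cortex and 2 in dentate gyrus, also when adjusted over the list alone. Rorb, a nuclear receptor gene (chromosome 19, 18930605 to 19111196, minus strand), was at 331 ± 16.6 CPM in cortex and 16.5 ± 3.54 CPM in dentate gyrus. The homeobox gene Cux2 was at 17.2 ± 3.3 and 0.628 ± 0.266 CPM, and Lamp5 had a log2 change of -2.58 (SE 0.29). Rasgrf2 was higher in dentate gyrus (1.48, SE 0.14). For this list the camera adjusted p was 0.00679, the adjusted p was 0.330 with an estimated correlation, and it was 0.0979 without cortex replicate 2. Of 10 layer 6 and 6b markers, 3 were higher in cortex and 1 in dentate gyrus, or 5 and 1 when adjusted over the list alone. The count higher in cortex was 1 without cortex replicate 2 and 6 without dentate gyrus replicate 2. The forkhead gene Foxp2 was at 21.5 ± 1.96 and 1.8 ± 1.26 CPM, and Tle4, a transcriptional corepressor gene, was higher in dentate gyrus (1.28, SE 0.25). The camera adjusted p of 0.0652 fell to 0.0308 without cortex replicate 1, 0.0445 without dentate gyrus replicate 1 and 0.0184 without dentate gyrus replicate 2.

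The 2 libraries with genes unlike their group bear on these groups. Cortex replicate 1 held Car8, Ebf1, Ebf2 and Ebf3 at 411, 19.0, 36.8 and 22.6 CPM, against 1.44, 2.67, 2.05 and 2.05 CPM in cortex replicate 2. Dentate gyrus replicate 2 held Dcn, Dlk1 and Gpr101 at 114, 83.4 and 17.3 CPM, against 1.71, 0.11 and 0.055 CPM in replicate 1 and 10.5, 13.0 and 1.72 CPM in replicate 3. Apart from Car8, these genes were chosen after their values were seen. Of the 3009 calls, 1467 were also called in the same direction without both libraries, where 1578 were called in all.

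**Figure D3:**
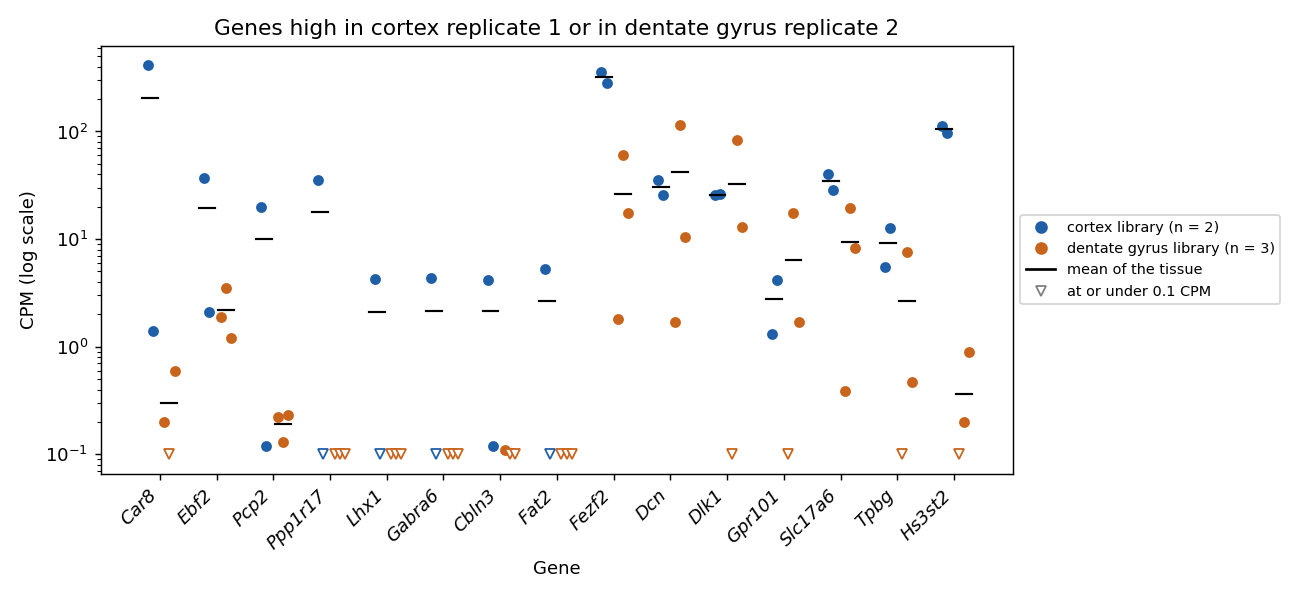
CPM on a log scale (vertical axis) is shown for 15 genes (horizontal axis), with a point for each cortex and dentate gyrus library, a line at the tissue mean, and open triangles for values at or under 0.1 CPM. Car8 was at 411 CPM in cortex replicate 1 and 1.44 CPM in cortex replicate 2, and Dcn at 114 CPM in dentate gyrus replicate 2.

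Interneuron genes were partly higher in cortex. Of 14 GABAergic interneuron markers, 7 were higher in cortex and 2 in dentate gyrus, or 8 and 2 when adjusted over the list alone. The count higher in dentate gyrus was 1 without dentate gyrus replicate 1 or without dentate gyrus replicate 3. The count higher in cortex was 4 without cortex replicate 1, 3 without cortex replicate 2 and 4 without dentate gyrus replicate 2. The somatostatin gene Sst (chromosome 16, 23889573 to 23890958, minus strand) was at 671 ± 41.6 CPM in cortex and 88.8 ± 21.5 CPM in dentate gyrus. Pvalb, a calcium-binding protein gene, was at 27.5 CPM in cortex replicate 1, the library with Car8 at 411 CPM, 11.7 CPM in cortex replicate 2 and 0.242 ± 0.203 CPM in dentate gyrus. The glutamate decarboxylase gene Gad2 had a log2 change of -1.74 (SE 0.25). The adenosine deaminase gene Adarb2 was higher in dentate gyrus (67.0 ± 17.2 against 4.73 ± 2.65 CPM). Camera gave an adjusted p of 0.00638, and the adjusted p was 0.371 with an estimated correlation.

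Non-neuronal markers were mostly low, and no such list passed camera. Of 13 astrocyte markers, 4 were higher in cortex and 1 in dentate gyrus, also when adjusted over the list alone, and 2 were higher in cortex without cortex replicate 2. Aldoc, an aldolase gene, fell from 108 ± 26.8 to 20 ± 1.64 CPM, and the bicarbonate cotransporter gene Slc4a4 rose from 60.5 ± 23.2 to 391 ± 61.4 CPM. Of 10 oligodendrocyte markers, the myelin genes Cnp and Ugt8a were higher in cortex, with adjusted p of 0.0129 and 0.0150 that became 0.108 and 0.234 without cortex replicate 2. The camera adjusted p of that list was 0.262, and it was 0.0323 without cortex replicate 1. Of 6 oligodendrocyte precursor markers, Lhfpl3 was higher in cortex, with an adjusted p of 0.0400 that became 0.201 without cortex replicate 2. None of 5 microglia, 10 vascular or 5 thalamic markers was called by edgeR, and the thalamic and vascular medians were 2.21 and 2.37 CPM in dentate gyrus. The microglia gene Cx3cr1 was called higher in cortex by DESeq2 (adjusted p 0.0284), by limma voom (0.0186), with the stricter filter (0.0381), without a filter (0.00837) and without dentate gyrus replicate 2 (0.0327). Of 6 choroid plexus and ependymal markers, Kl was higher in dentate gyrus and Otx2 in cortex. Kl had an adjusted p of 0.0932 without cortex replicate 1 and dentate gyrus replicate 2 together. The Otx2 adjusted p of 0.0384 was 0.372 without cortex replicate 2. Of 6 meningeal fibroblast markers, the proteoglycan gene Lum was higher in dentate gyrus, at 4.45 ± 0.993 CPM against 1 count over the cortex libraries. Dcn, also on this list, was not called. It was at 114 CPM in dentate gyrus replicate 2, against 1.7 and 10.5 CPM in replicates 1 and 3. Of 5 striatal projection neuron markers, 2 were higher in cortex, among them Ppp1r1b, with an adjusted p of 0.0351 that became 0.321 without cortex replicate 2. The striatal camera adjusted p was 0.428, and 0.0455 without cortex replicate 1. Of the red blood cell markers, only Alas2 was tested, at 0.367 ± 0.319 CPM in dentate gyrus and 0 counts in cortex, and it was not called.

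Activity-regulated genes were higher in cortex. Of 14 immediate early genes, 13 were higher in cortex and 0 in dentate gyrus, and 13 and 1 when adjusted over the list alone. Without cortex replicate 1 the count higher in cortex was 5, without cortex replicate 2 it was 9, and with a replicate block it was 9. Egr1, a zinc finger transcription factor gene (chromosome 18, 34859823 to 34864984, plus strand), was at 1181 ± 158 CPM in cortex and 89.8 ± 17.9 CPM in dentate gyrus. The phosphatase gene Dusp1 was at 141 ± 46.2 and 11.5 ± 4.12 CPM, the cytoskeletal gene Arc at 178 ± 49.1 and 18.8 ± 6.65 CPM, and the nuclear receptor gene Nr4a1 at 47.8 ± 15.8 and 1.73 ± 1.07 CPM. The remaining gene, Btg2, chosen after its values were seen, had a log2 change of 1.25 and an adjusted p of 0.116. The list median was -2.76 and the camera adjusted p was 1.44e-10, or an adjusted p of 0.330 with an estimated correlation.

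Neurofilament genes that passed were higher in cortex, while channel genes differed in both directions. Of 4 neurofilament genes, Nefh (156 ± 2.34 against 26.5 ± 1.99 CPM) and Nefm (2042 ± 51.7 against 915 ± 62.2 CPM) were higher in cortex, and 3 were when adjusted over the list alone. Of 26 potassium channel genes, 10 were higher in cortex and 8 in dentate gyrus, or 12 and 10 when adjusted over the list alone. The count of potassium channel genes higher in dentate gyrus was 3 without cortex replicate 1 and 5 without cortex replicate 2 or without dentate gyrus replicate 1 or 2. Kcna2 had a log2 change of -1.59 (SE 0.11), Kcnh5 one of -2.39 (SE 0.25) and Kcnq5 one of -2.81 (SE 0.33). Of 12 sodium and HCN channel genes, 5 were higher in cortex and 2 in dentate gyrus, or 8 and 2 when adjusted over the list alone. Scn1a was higher in cortex (252 ± 27.2 against 44.8 ± 7.76 CPM), and the subunit genes Scn3a and Scn3b were higher in dentate gyrus (1.67, SE 0.16 and 1.87, SE 0.17). The camera adjusted p was 0.000484 for neurofilament, 0.0261 for potassium channel and 0.0215 for sodium and HCN channel genes. The adjusted p was 0.330, 0.330 and 0.427 with an estimated correlation, and that of potassium channel genes was 0.113 without cortex replicate 2. Of 18 calcium channel genes, 8 were higher in cortex and 5 in dentate gyrus, or 9 and 5 when adjusted over the list alone, and 5 were higher in cortex without cortex replicate 1 or without cortex replicate 2. Cacna1e (1.24, SE 0.11) and Cacna1c (1.08, SE 0.15) were higher in dentate gyrus, and the list had a camera adjusted p of 0.504.

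Receptor genes also divided. Of 22 glutamate receptor genes, 7 were higher in dentate gyrus and 4 in cortex, or 8 and 8 when adjusted over the list alone, and 3 and 4 when the change had to exceed 2-fold. The AMPA receptor genes Gria1 (1.65, SE 0.15) and Gria2 (0.92, SE 0.14) and the kainate receptor gene Grik2 (1.60, SE 0.18) were higher in dentate gyrus. The list had a median of 0.15, a mean of -0.16 and a camera adjusted p of 0.6. Of 12 GABA-A receptor genes, 6 were higher in dentate gyrus and 2 in cortex, or 7 and 3 when adjusted over the list alone, and 0 were higher in cortex without cortex replicate 1. Gabra5 (1.17, SE 0.12) and Gabra4 (1.08, SE 0.14) were among the 6, and the camera adjusted p was 0.130. Of 26 monoamine and acetylcholine receptor genes, 12 were higher in cortex and 3 in dentate gyrus, or 12 and 4 when adjusted over the list alone. Without cortex replicate 2, 7 were higher in cortex, and without dentate gyrus replicate 3, 1 was higher in dentate gyrus. The nicotinic subunit gene Chrna4 (-3.11, SE 0.41) and the serotonin receptor gene Htr2a (-3.06, SE 0.47) were higher in cortex. The dopamine receptor gene Drd5 was at 13.7 ± 6.33 CPM in dentate gyrus and 0.172 ± 0.163 CPM in cortex. For these genes the camera adjusted p was 0.0215, the adjusted p was 0.576 with an estimated correlation, and it was 0.113 without cortex replicate 2.

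Of 15 neuropeptide and neurotrophin genes, 6 were higher in cortex and 2 in dentate gyrus, or 7 and 4 when adjusted over the list alone. The cholecystokinin gene Cck was at 1107 ± 88.7 CPM in cortex and 325 ± 23.9 CPM in dentate gyrus, and Vgf had a log2 change of -3.48 (SE 0.46). The neurotrophin gene Ntf3 was higher in dentate gyrus (22.2 ± 11.2 against 1.93 ± 0.871 CPM). For this list the camera adjusted p was 0.00679, the adjusted p was 0.330 with an estimated correlation, and it was 0.0991 without cortex replicate 2. Of 14 nuclear receptor genes, 4 were higher in cortex and 2 in dentate gyrus, or 5 and 2 when adjusted over the list alone. The count higher in dentate gyrus was 1 without dentate gyrus replicate 1, without dentate gyrus replicate 3 and with a replicate block. It also fell when either cortex library was left out. Rora (-2.49, SE 0.15) and Thrb (-1.89, SE 0.22) were higher in cortex, and the mineralocorticoid receptor gene Nr3c2 was higher in dentate gyrus (177 ± 32.3 against 30.4 ± 1.69 CPM). Nuclear receptor genes had a camera adjusted p of 0.00638, or an adjusted p of 0.330 with an estimated correlation.

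Adhesion and guidance genes included some of the clearest differences. Of 40 axon guidance genes, 13 were higher in dentate gyrus and 8 in cortex, or 14 and 12 when adjusted over the list alone. The count higher in cortex was 4 without cortex replicate 1 and 5 without cortex replicate 2. Sema5a, a semaphorin gene (chromosome 15, 32244810 to 32696341, plus strand), was at 2293 ± 81.7 CPM in dentate gyrus and 55.1 ± 16.6 CPM in cortex. Plxna4 (1.98, SE 0.13), Epha7 (2.05, SE 0.17) and Slit1 (2.60, SE 0.28) were also higher in dentate gyrus. The list had a median of -0.14, a mean of 0.03 and a camera adjusted p of 0.130. Of 23 cadherin and delta protocadherin genes, 8 were higher in dentate gyrus and 7 in cortex, or 8 and 11 when adjusted over the list alone. The balance was not stable, with 6 higher in dentate gyrus and 9 in cortex under either other scaling, 5 and 8 with a replicate block, and 4 and 6 without cortex replicate 1. Leaving out any single library gave more genes higher in cortex than in dentate gyrus. Pcdh20 was at 203 ± 19.5 and 7.24 ± 0.322 CPM, and Cdh9 at 96.9 ± 9.7 and 9.72 ± 0.76 CPM. The list had a median of -0.56 and a mean of -0.71 but a camera direction toward dentate gyrus, with an adjusted p of 0.839.

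Of 73 oxidative phosphorylation genes, 10 were higher in cortex and 0 in dentate gyrus, or 7 and 0 when adjusted over the list alone. These counts were 5 and 2 without cortex replicate 1, 6 and 0 without cortex replicate 2, and 3 and 1 without cortex replicate 1 and dentate gyrus replicate 2 together. Sdha was at 319 ± 33.6 and 150 ± 19.4 CPM, and Cox4i1 at 113 ± 16.8 and 50.6 ± 1.38 CPM. The camera adjusted p of 0.0416 became 0.692 with an estimated correlation and 0.113 with a replicate block. It was 0.188 without cortex replicate 1, and 0.0629, 0.0510 and 0.0983 without dentate gyrus replicates 1, 2 and 3. Of 72 ribosomal protein genes, 2 were higher in dentate gyrus and 1 in cortex, and 0 when adjusted over the list alone, with a camera adjusted p of 0.511. Without cortex replicate 1 these counts were 1 and 0. The median CPM of this family was 6.62 in cortex and 8.29 in dentate gyrus. Reads shared between near-identical copies may lower this level, which was not measured.

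**Figure D4:**
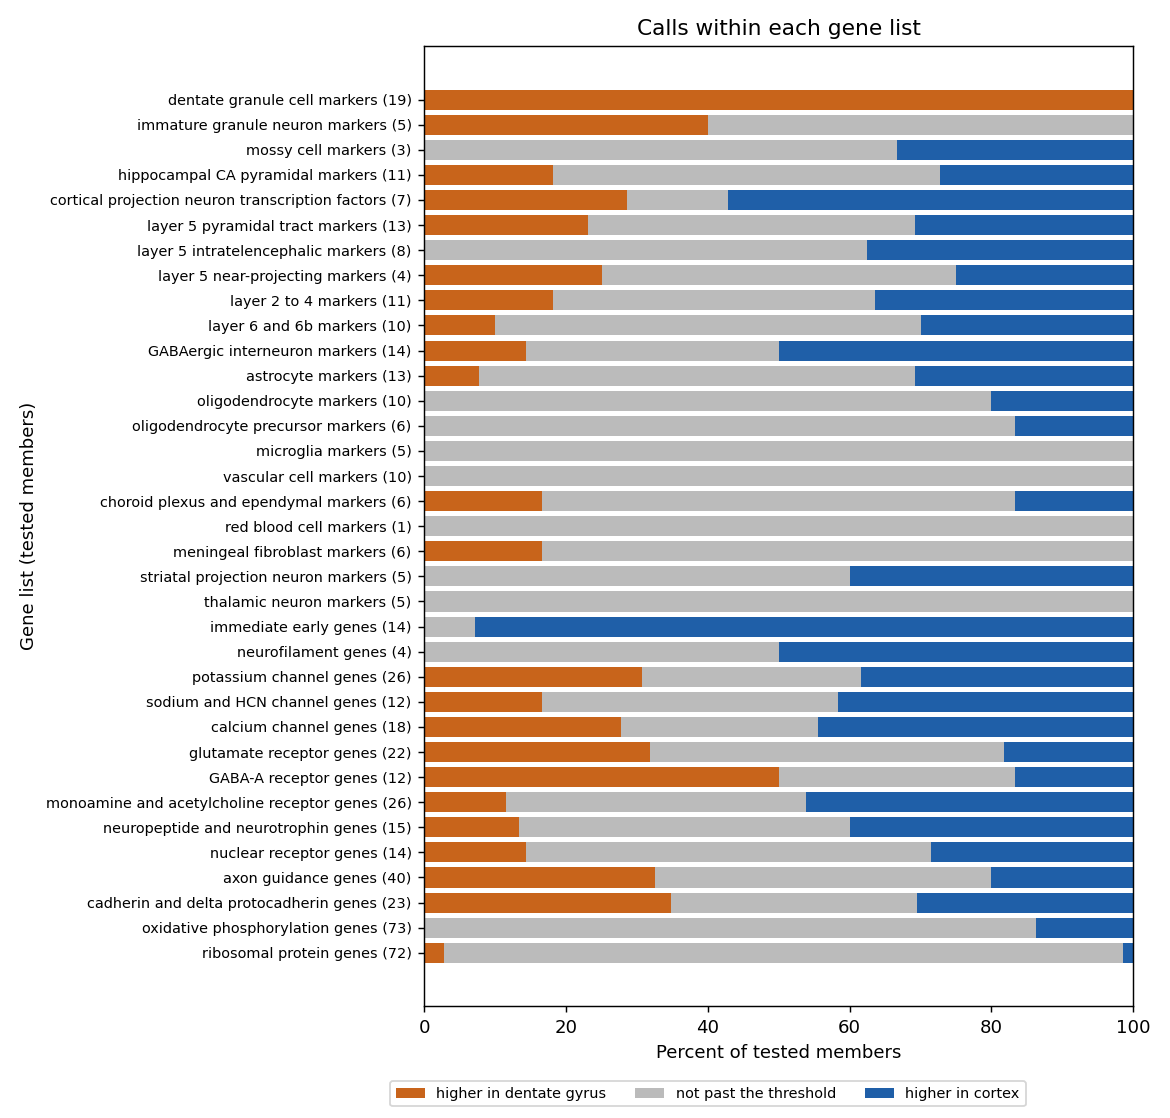
Bars give the percent of tested members (horizontal axis) that were higher in dentate gyrus, not past the threshold or higher in cortex for each of 35 gene lists (vertical axis, number of tested members in parentheses). All 19 dentate granule cell markers were higher in dentate gyrus, and 13 of 14 immediate early genes were higher in cortex. The latter count fell to 9 with a replicate block. It also fell when either cortex library was left out, which leaves a lone cortex library.

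Over the 34 lists tested, camera called 12, of which 1 was toward dentate gyrus and 11 toward cortex. With an estimated correlation 0 lists were called by camera, while fry called 16 for movement in one direction and 29 for change in either direction.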

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

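Removal of Rn45s and of cortex replicate 1 together with dentate gyrus replicate 2 were the settings chosen after the data were seen. The 3009 calls became 3021 with relative log expression scaling, 3001 with upper-quartile scaling, 3792 without a filter, 3027 with a stricter filter, 3043 with robust dispersion, 3009 without Rn45s, 4199 by DESeq2 and 3426 by limma voom. Leaving out single libraries gave 1886 to 2775 calls, 908 to 1276 higher in dentate gyrus and 913 to 1499 higher in cortex, and the lowest counts leave cortex with a lone library that is assumed to vary like the others. Without cortex replicate 1 and dentate gyrus replicate 2 there were 1578 calls, 771 higher in dentate gyrus and 807 higher in cortex, and fewer libraries lower the count by construction. A test for changes above 2-fold called 842 genes, 360 and 482 by direction, all of them among the 3009. Among the called genes, 1 changed sign without cortex replicate 1 and was not called there, and no shared call changed direction in any of these settings.

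Whether libraries with the same replicate number share an animal is not stated. The correlation across genes of the difference between replicates 1 and 2 was -0.012 between tissues. This cannot decide the question, because it rests on a single difference in each tissue. With a replicate block 2237 genes were called, 1111 and 1126 by direction, and 13 lists.

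Camera called 12 lists, 7 with the stricter filter and 0 with an estimated correlation, against 16 by fry. The cause of these gaps was not tested. With a correlation estimated from 5 libraries, even the list with all 19 members higher in dentate gyrus had a camera adjusted p of 0.116. That setting therefore does not tell the lists apart. Over lists and settings, 27 calls were lost and 13 gained, and for named genes 128 were lost and 23 gained, with 0 reversed. The test for changes above 2-fold accounts for 40 of the 128. The gap between the lowest correlation within a tissue and the highest between tissues was 0.0567, and 0.4841 with the 500 most variable genes, which are selected for spread. Depth limits genes near the floor. Recovery of 2-fold changes was 24.2% in the simulation, where far fewer genes changed than were called here, so recovery here is not known. Genes that were not called may therefore still differ.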

Other observations

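Genes with the smallest p-values outside the lists, chosen after their values were seen, were mostly higher in dentate gyrus. Ppp3ca, a calcineurin catalytic subunit gene, was at 7311 ± 100 CPM in dentate gyrus (SD, n = 3) and 1363 ± 56.6 CPM in cortex (SD, n = 2), with an edgeR adjusted p of 4.18e-07. Wipf3, an actin regulator gene, was at 4695 ± 533 and 356 ± 28.5 CPM. The transcription factor genes Zbtb20, Foxo1 and Zeb2 were at 301 ± 26.8, 470 ± 50.8 and 2559 ± 162 CPM in dentate gyrus and 12.6 ± 2.58, 36.5 ± 4.45 and 586 ± 12.5 CPM in cortex. Synpr, a synaptic vesicle protein gene, was at 419.5 ± 37.6 and 43.4 ± 4.7 CPM. Toward cortex, the growth factor gene Ptn was at 257 ± 9.7 CPM against 14.7 ± 1.19 CPM, and the G protein subunit gene Gng3 at 916 ± 15.9 against 178 ± 13.3 CPM.

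Xist, transcribed from the inactive X chromosome, and the Y-linked genes Ddx3y, Kdm5d and Eif2s3y were present in each of the 5 libraries, also chosen after their values were seen. Xist was at 18.0 and 11.7 CPM in cortex and 63.0, 37.0 and 54.8 CPM in dentate gyrus replicates 1, 2 and 3. Ddx3y was at 24.2 and 21.2 CPM in cortex and 6.79, 16.8 and 14.3 CPM in dentate gyrus. The Y-linked genes did not move together, since Kdm5d was at 5.39 and 7.39 CPM in cortex and 3.15, 22.8 and 16.8 CPM in dentate gyrus, and Eif2s3y at 4.85 and 7.26 CPM and at 4.5, 11.8 and 3.41 CPM.

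The weighing below used tests chosen after the result was seen for dentate gyrus replicate 2 and for the pooled cerebellar markers. The Purkinje, granule cell, GC content and length tests were set beforehand.

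Cortex replicate 1 held Car8 at 411 CPM and Ebf2 at 36.8 CPM, against 1.44 and 2.05 CPM in replicate 2. A candidate source is RNA of cerebellar cells, since 4 of 5 cerebellar granule cell markers were at least 3-fold higher in replicate 1, among them Gabra6 (4.33 CPM against 0), Fat2 (5.33 against 0) and Cbln3 (4.13 against 0.12). Of 10 Purkinje cell markers 6 were at least 3-fold higher, short of the 7 set beforehand, so Purkinje cells cannot be told apart from other sources by that count. Ppp1r17 and Pcp2 were at 35.7 and 19.7 CPM against 0 and 0.12, while Itpr1 was at 840 and 963 CPM in cortex replicates 1 and 2. After that shortfall the lists were pooled, and of 9 markers at or under 1 CPM in replicate 2, 8 were at least 3-fold higher in replicate 1, against 28.7% of 3743 other such genes (one-sided Fisher's exact p = 0.000313); whether such RNA came from tissue, another library or tagged cells stays open, and no biological explanation was tested.

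Dentate gyrus replicate 2 held projection neuron genes, with Fezf2 at 18.9% of its cortex level (counting interval 17.9% to 20%). Neocortical RNA of the makeup of the cortex libraries would bring every cortex-restricted gene at 1 common share. Such genes were selected as low in dentate gyrus replicate 1, without the other dentate gyrus libraries. The median of 39 such genes was 5.52% (quartiles 2.53% and 16.5%) against 4.34% in replicate 3. Fezf2, itself among the 39, was 3.43 times that median. Of the 39, 12 were over 10% and 8 were under 2%. A ratio for 1 gene, tested after its value was seen, therefore cannot decide the question. Only 43.6% of the genes lay within 2-fold of the median, against 100% for the ratio of cortex replicate 1 to 2. Selection for expression in both cortex libraries favoured that 100%. In dentate gyrus replicate 3 the percents also spread, from 0% (Herc6) to 50.3% (Dlk1). The spread therefore does not decide whether a common neocortical share was present in dentate gyrus replicate 2. Dcn and Dlk1, chosen after their values were seen, stood at 374% and 323% of cortex. Dcn is also a member of the meningeal fibroblast list, and a meningeal source was not tested. Across all genes, however, dentate gyrus replicate 2 was the dentate gyrus library closest to cortex (Spearman 0.8967 and 0.894, against 0.8841 and 0.8817 for replicate 3). Neocortical RNA, of the makeup of the cortex libraries or of another, stays open. Subiculum neurons are another candidate, as 4 of 4 detected members of a short list (Fn1, Nts, Slc17a6 and Tpbg, at 19.0, 0.666, 19.4 and 7.55 CPM, with Ly6g6e at 0) were highest in that dentate gyrus library (exact one-sided binomial p = 0.0123). That list was drawn up after these values were seen, and S100b, drafted with it and dropped once its values were known, was not highest, which gives 4 of 5 and an exact binomial p of 0.0453. The subiculum therefore cannot be told apart from other sources, because the list is short and was not independent of the values, Fn1 was at 16.0 CPM in dentate gyrus replicate 1, and in cortex replicates 1 and 2 Slc17a6 was at 39.9 and 28.8 CPM, Nts at 2.17 and 4.88 CPM and Tpbg at 5.56 and 12.7 CPM.

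Immediate early genes were lower in dentate gyrus, with a median log2 change of -2.76 over 14 genes. These genes are richer in GC than the rest (median 54.8% against 49.4%), but after a GC content trend was removed the median was -2.46 (quartiles -3.49 and -1.42). After a transcript length trend was removed it was -2.70. These trends alone do not account for the difference. The tissue itself, the activity of the animals and the time between dissection and lysis stay open and were not tested.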
